A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

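The study measured poly(A)-selected RNA from Schizosaccharomyces pombe, the fission yeast, in 4 strains with 3 samples each: wild type, a strain lacking med20 (med20Δ), a strain lacking rrp6 (rrp6Δ) and a strain lacking both. Per the labels' protocols, cells were grown in rich medium to log phase, RNA was extracted with hot phenol, polyadenylated RNA was selected with oligo(dT), and strand-marked (dUTP) libraries were sequenced. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 and compared with DESeq, whose version is not given in the sources used here. The genome build, the annotation, the program that counted reads per gene and its strand setting are not given in the sources used here either. Oligo(dT) selection favours RNA with a poly(A) tail, so the level of a tRNA, rRNA, snRNA or snoRNA in these libraries reflects both its amount and the share of it that carries a tail or escaped the selection.

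The deposited files are 3 comparison tables, 1 for each mutant against wild type, with 6888 genes in the med20Δ and rrp6Δ tables and 6871 in that of the double mutant. The 17 genes not listed in the table of the double mutant were all at the lowest possible value in wild type. Per the file headers, the authors give the mean normalised signal of each group (gene counts divided by the size factor of each library and averaged), the fold change as the ratio of those means, its log2 value, a p-value and an adjusted p-value. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment over all genes of a table. The lowest mean in each group equals a count of 1 in each library (3 counts over a group), so a fold against wild type at that floor is a lower bound. The tables hold no column for a single library, and every library in the text was recovered as described next.

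The planned per-gene test needed values for each replicate. Since the tables hold group means, genes were called, as the plan provided for that case, at a deposited adjusted p under 0.05, and no test was available for the double mutant against either single mutant or for the interaction, which were described by differences of deposited log2 fold changes of at least 1. The tables carry enough digits for each group mean to be split into the whole counts of its 3 libraries. These counts were recovered for 100% of wild-type means, 96.8% of med20Δ means, 97.0% of rrp6Δ means and 96.1% of means of the double mutant, with 6566 genes solved in all 12 libraries; the means left unsolved were high, from 6591 upward. Tested on simulated counts, the method made no error for 3 of the groups and gave 56 wrong splits of 3986 solved in rrp6Δ, all at means of 379 or more. It solved 57.9% of the simulated rrp6Δ means, far below the 97.0% of the real table, so for that strain the simulation does not match the real recovery. Libraries are numbered within a strain by their recovered step and do not correspond to the replicate letters of the labels. The series design names 3 biological replicates per strain, but the labels do not say whether these were separate cultures. The p-values measure the spread between these samples, part of which may be technical.

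The recovered counts fed a test chosen after seeing the data: limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(count divided by size factor + 1), over 5990 genes with counts in all 12 libraries and a mean of at least 10 over them, with all 4 strains in 1 model and Benjamini-Hochberg adjustment within a comparison. The log2 fold changes of this test are on the log2(value + 1) scale and understate changes of low genes. In data simulated for the med20Δ comparison with 5754 genes tested, it called 96.0% of genes raised 4-fold and 98.0% of genes lowered 4-fold, 30.0% and 32.0% of genes changed 2-fold up and down, and 11 unchanged genes. Every standard deviation comes from the recovered counts (n = 3), and standard errors come from limma. Recovered levels are scaled by the size factors of the table they stand beside, or over all 12 libraries in comparisons among mutants, so the level of a gene differs slightly between paragraphs.

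The 33 gene lists were fixed before the data were examined, as were the grouping, the test for each kind of file, the alternative settings and the rule for naming genes. They are Mediator subunits, the exosome and its cofactors, meiotic transcripts targeted by Mmi1, genes named for meiotic expression, cytosolic ribosomal proteins, ribosome biogenesis, the RNA polymerase III machinery, tRNA, snoRNA, snRNA, rRNA and other non-coding RNA genes, Tf2 retrotransposons, subtelomeric genes, heterochromatin and RNAi factors, cell separation, flocculation, core stress, chaperones, phosphate, iron, nitrogen starvation, glucose and carbon use, M-cell and P-cell specific genes, the mating pheromone response, auxotrophy markers, pyrimidine and leucine synthesis, histones, S-phase genes under the MBF factor, mitosis, centromere and kinetochore, and housekeeping controls. For each list, called members were counted per direction and compared with all other genes by a two-sided Fisher's exact test, and the list's median log2 fold change was placed among 10000 random lists matched on mean expression in 20 bins, each with Benjamini-Hochberg adjustment over lists (and over both directions for Fisher's test). RNA classes were compared by Fisher's exact test on genes called higher against lower, inside and outside the class. The percentile test gave a p under 0.05 for 3 of 100 random lists. As an addition, camera (limma) tested each list with a preset correlation of 0.01 and with an estimated correlation. It covered the members with recovered counts in all 12 libraries and a mean of at least 10 over them. These are 31 tRNA genes and 23 ribosomal protein genes. The snoRNA, snRNA and other non-coding RNA lists were drawn by name or identifier and hold 56, 10 and 1503 genes in the single-mutant tables. The annotated classes hold 51, 7 and 1501, and 3 of the 10 in the snRNA list are annotated as protein-coding.

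Genes were named by rule: med20, rrp6 and the markers ura4, leu1 and his2; the 6 protein-coding and 3 non-coding genes with the largest change in each direction among called genes with a mean of at least 50 and replicate values that do not overlap, or that were not recovered, as for SPAC27D7.09c in med20Δ; and the called list members with a mean of at least 50 and the largest change in each direction. Genes named outside the rule, as for small counts, were chosen after their values were seen. Gene symbols were matched to a reference annotation for 6785 of 6888 identifiers, used for names and neighbours only, without coordinates. Alternatives covered other thresholds, other filters on low counts, re-centring on the median protein-coding gene, adjustment over other sets of genes, calls with a minimum fold, the limma test, voom weights, other pseudocounts, leaving out each library, and the term for the library of each strain that stood apart. A count-based negative binomial test was not run, since the deposited values are not counts, and it was left out for the recovered counts as well, where it was possible. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

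Totals over the genes solved in all 12 libraries, which leave out the most abundant genes, ran from 6338353 to 9845280 counts per library. The wild-type libraries, solved in full, held 21250618, 21179187 and 20125200 counts. All 12 libraries differed from the others of their strain by more than sampling noise (chi-square per degree of freedom from 24.5 to 157), so none was counted as a duplicate. On the first component of the within-strain differences of 4513 protein-coding genes, which held 52.9% of that variance, 1 library of each strain stood apart: wild type 1, rrp6Δ 2, med20Δ 1 and double mutant 2. These are also the libraries with the lowest 5.8S rRNA in their strain. They are treated below as a possible batch, with tRNA, 5.8S rRNA and snRNA totals and differences in 5S rRNA given separately for them, and gene and list results given for all libraries. Reads are not independent molecules, so bounds from the floor cover counting error only.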

Results

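RNA levels were measured in 4 strains of fission yeast with 3 samples each: wild type, med20Δ, rrp6Δ and the med20Δ rrp6Δ double mutant. Med20 is a subunit of Mediator, the complex that connects transcription factors with RNA polymerase II, and Rrp6 is an exonuclease of the nuclear exosome, which degrades and trims RNA. The question was how loss of Med20 affects tRNA and other non-coding RNA genes, with rrp6 deleted so that transcripts the exosome removes become visible. The values are the authors' mean normalised counts per strain, and libraries recovered from them held 6338353 to 9845280 counts in the genes they share. Fold changes, log2 fold changes and adjusted p-values (DESeq, Benjamini-Hochberg) are the authors' unless limma is named, and levels with a standard deviation (SD, n = 3) come from the recovered counts. Genes said to have changed most are those with a mean of at least 50. Members of near-identical families (tRNA and rRNA copies, ribosomal protein pairs, Tf2 elements) and antisense RNAs are uncertain as single genes, because how reads were assigned to copies and strands is not given in the sources used here.

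The deleted genes were read first. In recovered counts med20 went from 604 ± 21.7 to 4.27 ± 1.87 in med20Δ and from 734 ± 29.2 to 25.9 ± 5.11 in the double mutant (SD, n = 3 each), each pair being scaled as in its own table. The rrp6 level went from 1549 ± 498 to 1.51 ± 1.10 in rrp6Δ and from 1675 ± 537 to 1.26 ± 0.595 in the double mutant. The authors' deposited tables give med20 log2 fold changes of -7.14 in med20Δ and -4.82 in the double mutant (adjusted p = 8.85e-46 and 5.8e-23). For rrp6, the authors' deposited tables give -10.01 in rrp6Δ and -10.38 in the double mutant (adjusted p = 3.69e-28 and 3.39e-28). Per the labels, the strains carry different mating types and auxotrophic alleles, which differ with the deletion. The marker ura4, a pyrimidine synthesis gene, went against 1 label. Labels name the allele ura4-D18 for med20Δ, yet recovered ura4 counts were 1945 ± 325 in wild type and 2073 ± 269 in the libraries labelled med20Δ. In the double mutant ura4 went from 2359.9 ± 385 to 3.39 ± 1.84 (limma against the libraries labelled med20Δ, log2 -9.25 ± 0.26 SE, adjusted p = 5.71e-11). Its neighbours tam14 and new25 had means of 342 and 483 in wild type and of 40.2 and 33.5 in the double mutant in the authors' deposited table (adjusted p = 9.65e-10 and 2.66e-15). Beside med20Δ, the authors' deposited table has them at 282 and 398 in wild type and at 249 and 403 in the libraries labelled med20Δ (adjusted p = 1 for both). The marker his2 fell in the double mutant (log2 -1.17, adjusted p = 0.00988) in the authors' deposited table. It was not called in med20Δ or rrp6Δ, with log2 values of -0.49 and -0.06 in the authors' deposited tables (adjusted p = 0.621 and 1). For leu1, not called in any mutant, the authors' deposited tables give 0.17, -0.38 and -0.67 (adjusted p = 1, 0.674 and 0.147).

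**Figure D1:**
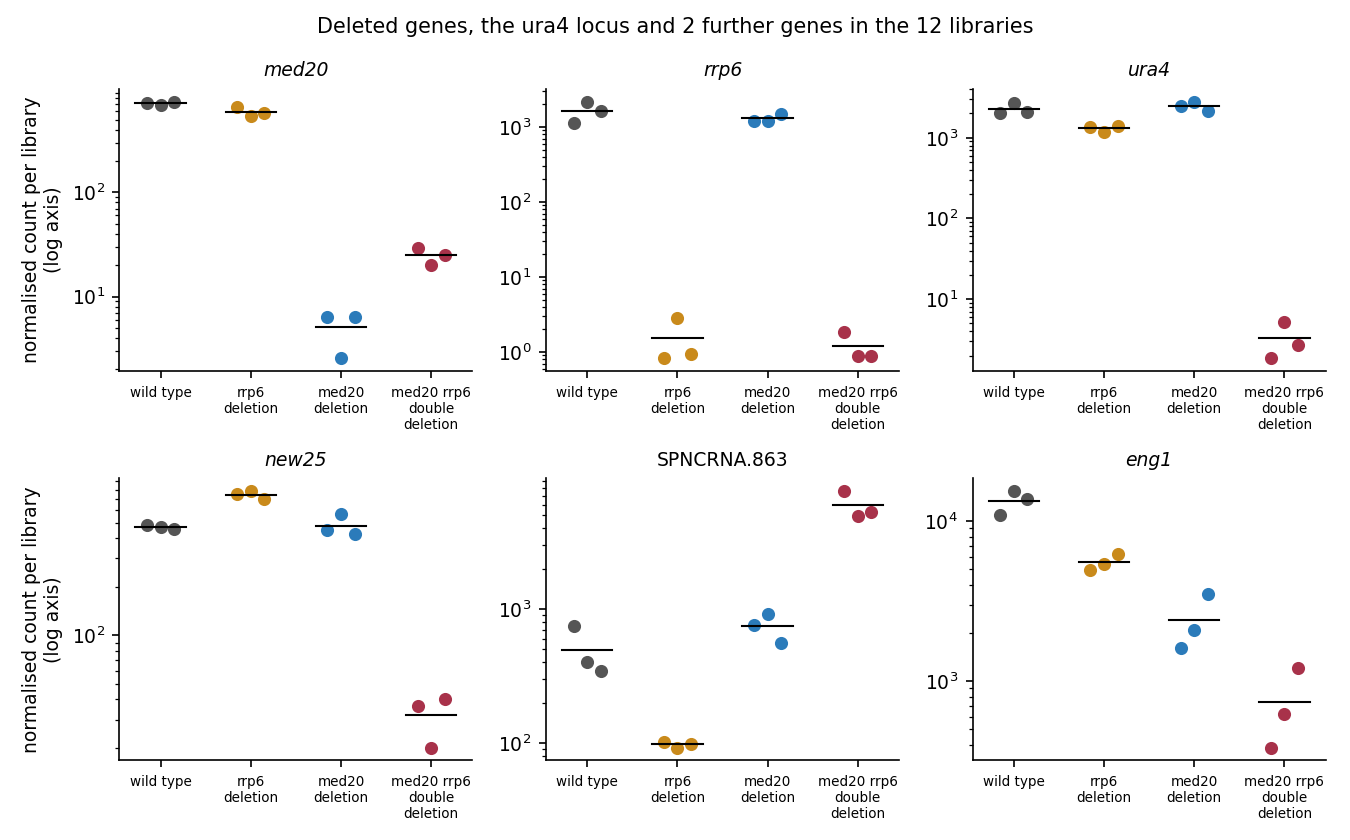
Normalised counts of med20, rrp6, ura4, new25, SPNCRNA.863 and eng1 in each of the 12 libraries on a log axis, with a bar at the mean of each strain's 3 libraries. The libraries labelled med20Δ hold ura4 and new25 near wild type while the double mutant does not, and SPNCRNA.863 is lowest in rrp6Δ and highest in the double mutant.

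In med20Δ, 6 of 10 cell separation genes were called lower and 5 of 25 core stress genes higher, though neither list passed camera with an estimated correlation. The endoglucanase gene eng1, whose product digests the division septum, went from 11335 ± 1931 to 2027 ± 831 (SD, n = 3 each) in recovered counts, and the small heat-shock gene hsp9 from 3785 ± 2119 to 15006 ± 3972. In the authors' deposited table, eng1 fell by 2.48 on the log2 scale (adjusted p = 1.23e-11) and hsp9 rose 3.96-fold (adjusted p = 0.000202). Calls in the authors' deposited table number 163 of 6888 genes, 77 higher and 86 lower, of which 41 and 53 are protein-coding and 34 and 33 non-coding RNA.

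Of 10 cell separation genes, 6 fell (8 adjusted over the list alone), against 1.16% of other genes, with the septum glucanase agn1 at -1.85 and adg1 at -2.09 in the authors' deposited table. For this list Fisher's exact test gave an adjusted p = 4.23e-08 and camera an adjusted p = 0.336 with an estimated correlation. Of 25 core stress genes, 5 rose (6 adjusted over the list alone): the metallothionein zym1 (3.91-fold), the protease isp6 (2.43-fold), hsp9, the peroxidase gpx1 (2.46-fold) and hsp20 (2.13-fold) in the authors' deposited table. The adjusted p was 0.000225 by Fisher's exact test, and camera gave adjusted p = 0.556 with an estimated correlation. Of 17 flocculation genes, 3 fell (3 adjusted over the list alone), which were pfl7, pfl3 and cbf12 at -2.47, -1.82 and -1.72 in the authors' deposited table. Against all other genes this had an adjusted p = 0.0149 (Fisher's exact test) and, in camera, an adjusted p = 0.556 with an estimated correlation. Among 1503 other non-coding RNAs, 34 rose and 33 fell (46 and 44 adjusted over the list alone; Fisher's exact test, adjusted p = 0.000229 and 0.00852; camera, adjusted p = 0.881 with an estimated correlation). The subtelomeric list had a median of -0.62, below the matched random lists (adjusted p = 0.000943, from the smallest p that 10000 lists can give; camera, adjusted p = 0.556 with an estimated correlation), and mfs1 and SPAC977.15 were its only called members of 48, both lower (3 adjusted over the list alone).

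Of 165 tRNA genes, only SPBTRNAASN.01 rose (4.22-fold, adjusted p = 0.0456, in the authors' deposited table; 0 adjusted over the list alone), although 146 had a positive log2 fold change and the median of 0.37 lay above the matched random lists (adjusted p = 0.000943; camera, adjusted p = 0.604 with an estimated correlation). The 146 include any tRNA gene at the floor in both strains, since the floor was 1.00256 in wild type and 1.00698 in med20Δ. The 46 rRNA genes had a median of 1.25 (adjusted p = 0.000943; camera, adjusted p = 0.604 with an estimated correlation) with no call among them. Only snoU18 rose among 56 snoRNA genes (5.20-fold in the authors' deposited table; 1 adjusted over the list alone), whose median was 0.53 (camera, adjusted p = 0.604 with an estimated correlation). The 57 ribosome biogenesis genes had a median of -0.33 (adjusted p = 0.000943; camera, adjusted p = 0.604 with an estimated correlation) and likewise no call. Adjusted over the list alone, 1 of 8 phosphate genes, 1 of 22 Mediator subunits (med20) and 2 of 26 glucose and carbon genes were lower, 1 of the latter was higher, and of 19 nitrogen starvation genes 1 was higher and 1 lower. Single list members called in the authors' deposited table were pho84, the phosphate transporter (-1.63), put4, a proline transporter (-1.61), and in the glucose and carbon list mae2 (-1.55) and ght7 (-2.11). Other medians that passed the percentile test in the authors' deposited table were those for snoRNA (0.53, adjusted p = 0.00147), subtelomeric genes (-0.62, adjusted p = 0.000943), chaperones (0.23, adjusted p = 0.0204), phosphate (-0.55, adjusted p = 0.0033), iron (0.42, adjusted p = 0.000943), glucose and carbon (0.33, adjusted p = 0.00147), mating pheromone (-0.36, adjusted p = 0.0421), cell separation (-1.30, adjusted p = 0.000943), flocculation (-0.30, adjusted p = 0.0291) and core stress (0.63, adjusted p = 0.000943). Camera with an estimated correlation passed none of them. The 22 lists without a call held 610 members, with 0 calls in the authors' deposited table (DESeq), 46 members at an unadjusted p under 0.05 and 12 calls of 447 by limma.

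The protein-coding genes that rose most were tsp0 (5.35-fold), SPAC11D3.01c (5.14-fold), pbi2 (4.87-fold), SPAC15E1.02c (4.69-fold), SPAC27D7.09c (4.42-fold) and cmt2 (4.09-fold), with adjusted p-values from 7.69e-09 to 0.00228 in the authors' deposited table. SPBPB7E8.01 fell furthest after med20 itself (-3.55, adjusted p = 1.72e-22), followed by SPBPB10D8.01 and SPBPB10D8.02c, a predicted arylsulfatase (-2.97 and -2.89), in the authors' deposited table. Among non-coding RNAs, the authors' deposited table has SPNCRNA.1273, SPNCRNA.719 and SPNCRNA.1109 rising 8.17-, 7.88- and 7.83-fold. The authors' deposited table also puts SPNCRNA.1307, SPNCRNA.1277 and SPNCRNA.1471 lower, at -4.14, -3.01 and -2.93. SPNCRNA.1109 lies close to ura4, and SPNCRNA.1307 is annotated as antisense. The stress genes also move with the library of each strain that stands apart, 21 of 22 scoring positive on that component, and limma called 5 of them with all libraries but 1 without wild type 2, med20Δ 1 or med20Δ 2.

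In rrp6Δ, 246 of 1503 non-coding RNAs, 14 of 56 snoRNA genes and 8 of 11 Mmi1 targets were called higher, the snoRNA list without passing camera at an estimated correlation. SPNCRNA.942 went from 31.3 ± 16.9 to 1736 ± 117 (SD, n = 3 each) in recovered counts, the snoRNA snR91 from 93.8 ± 25.4 to 1994 ± 201, and rec11, which encodes a meiotic cohesin subunit, from 12.7 ± 2.13 to 273 ± 30.7. In the authors' deposited table these are increases of 55.5-, 21.3- and 21.5-fold (adjusted p = 1.21e-42, 2.07e-29 and 1.35e-21). Calls in the authors' deposited table number 411 of 6888 genes, 342 higher and 69 lower.

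Of 1503 other non-coding RNAs, 246 rose (319 adjusted over the list alone), 16.4% against 1.78% of other genes, and 5 fell (5 adjusted over the list alone), 0.333% against 1.19%. By Fisher's exact test the adjusted p was 8.98e-91 and 0.0202 for higher and lower, and by camera the adjusted p = 0.00178 with an estimated correlation for higher levels. SPNCRNA.1511 and SPNCRNA.242 followed SPNCRNA.942 at 48.3- and 37.5-fold, and beside the lower nc-tco1 and rse1, SPNCRNA.863, SPNCRNA.1471 and SPNCRNA.685 fell most, at -2.31, -1.71 and -1.46, in the authors' deposited table. Among 56 snoRNA genes, 14 rose (18 adjusted over the list alone), with sno12 at 23.2-fold and snR98 at 20.5-fold in the authors' deposited table. That share had an adjusted p = 8.1e-06 by Fisher's exact test, while camera gave an adjusted p = 0.367 with an estimated correlation. The tRNA list of 165 genes had 0 calls (DESeq), with 0 at an unadjusted p under 0.05, 0 by limma and 0 adjusted over the list alone, against 5.09% of other genes called higher (Fisher's exact test, adjusted p = 0.00626, a difference lost over genes with a mean of at least 10).

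Mmi1 binds meiotic transcripts in growing cells and passes them to the exosome. Of 11 such transcripts, 8 rose (11 adjusted over the list alone), with the meiotic transcription factor gene mei4 at 9.29-fold and ssm4 at 9.08-fold in the authors' deposited table. For this list Fisher's exact test gave an adjusted p = 1.63e-07 and camera an adjusted p = 0.00969 with an estimated correlation. Of 129 genes named for meiotic expression, which share members with that list, 16 rose (17 adjusted over the list alone), mug45 and meu1 most among those with a mean of at least 50, at 15.7- and 14.3-fold, and mug9, under that mean, 16.1-fold in the authors' deposited table. The adjusted p was 0.00799 by Fisher's exact test, and camera gave adjusted p = 0.0817 with an estimated correlation. Outside the lists, rec25 and mek1, both of meiotic recombination, rose 16.1- and 11.6-fold in the authors' deposited table.

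Called list members in rrp6Δ otherwise came in small numbers. In the authors' deposited table, genes that rose were the phosphate genes tgp1 (5.26-fold) and pho1 (3.59-fold), the subtelomeric nrg1 (8.75-fold) and tht2 (4.22-fold), gst2 (4.26-fold), the ammonium transporter amt3 (2.52-fold), rpl3002 (2.68-fold) and the exosome cofactor red1 (adjusted p = 0.0301). Those that fell in the authors' deposited table were rps1401 (-2.45), mfs2 (-2.16), SPAC212.12 (-1.88), SPBC1348.10c (adjusted p = 0.0379), ght7 (-1.84), mfm2 (-1.60), the Mediator gene med18 (-1.24), eng1 (-1.23), ura1 (-0.96) and the rRNA genes SPRRNA.33 (-1.96) and SPRRNA.03 (-1.83). By limma amt3 and mfm2 were not called. Adjusted over the list alone, genes higher and lower were 2 and 0 of 8 for phosphate, 3 and 4 of 48 for subtelomeric genes, 1 and 0 of 25 for core stress, 1 and 1 of 19 for nitrogen starvation, 1 and 1 of 141 for ribosomal proteins, and 1 and 1 of 18 for the exosome. They were 0 and 1 of 22 for Mediator, 0 and 5 of 10 for cell separation, 1 and 2 of 9 for M cells, 0 and 1 of 7 for pyrimidine and leucine, 0 and 1 of 26 for glucose and carbon, and 0 of 46 for rRNA genes. Protein-coding genes outside the lists that fell most in the authors' deposited table were SPAC750.08c (-2.85), aah2 (-1.90) and SPBPB7E8.01 (-1.90). The 13 Tf2 retrotransposon genes move with the libraries that stand apart, 0 of 13 scoring positive on that component, and none was called, with a median of 0.89 (percentile test, adjusted p = 0.000943; camera, adjusted p = 0.663 with an estimated correlation). Beside Tf2, medians that passed the percentile test in the authors' deposited table were those for tRNA (-0.34, adjusted p = 0.0284), rRNA (-0.55, adjusted p = 0.000943), subtelomeric (-0.38, adjusted p = 0.000943), cell separation (-0.68, adjusted p = 0.000943), glucose and carbon (-0.58, adjusted p = 0.000943), S phase (-0.38, adjusted p = 0.0173), nitrogen starvation (-0.27, adjusted p = 0.0406), M cells (-0.34, adjusted p = 0.041), ribosome biogenesis (-0.13, adjusted p = 0.0318), core stress (-0.03, adjusted p = 0.0352), snoRNA (0.59, adjusted p = 0.0249), Mmi1 targets (2.65, adjusted p = 0.000943) and other non-coding RNA (0.62, adjusted p = 0.000943). Camera with an estimated correlation passed the last 2. The ribosome biogenesis and core stress medians, though negative, lay above the matched random lists, at percentiles 99.48 and 99.37. The tRNA and M-cell medians equal the log2 ratio of the floors, 0.888013 in rrp6Δ over 1.1256 in wild type. The median gene of both lists thus lies at the floor in both strains, and its value shows no fall. For the 31 tRNA genes tested by limma the median was 0.19. The 17 lists without a call held 437 members, of which 19 had an unadjusted p under 0.05 (DESeq), and limma called 4 of 284. The median protein-coding gene was at -0.12 in this table and at -0.18 in that of the double mutant, and re-centring on it turned no call. Re-centring kept the deposited p-values, and a shift this small could turn only calls with very small fold changes.

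In the double mutant, genes called higher included tRNA genes, non-coding RNAs and snoRNAs, and genes called lower included ribosomal protein and cell separation genes. Of 164 tRNA genes, 52 rose and none fell (65 and 0 adjusted over the list alone), against 8.02% of other genes called higher, with a median of 2.72 when genes at the floor are taken at the floor. Against all other genes this had an adjusted p = 3.36e-16 (Fisher's exact test) and, in camera, an adjusted p = 0.125 with an estimated correlation. SPBTRNAGLN.01 was at least 154-fold higher, wild type being at the floor of 1 count per library, SPBTRNAARG.05 rose 109-fold and SPCTRNATHR.10 103-fold (adjusted p = 0.00484, 0.00724 and 0.0186) in the authors' deposited table. The fold of SPBTRNAARG.05 also rests on a wild type near the floor, at 1.94 ± 1.26 in recovered counts scaled over all 12 libraries. Recovered counts for SPCTRNATHR.10 went from 11.3 ± 9.56 to 1163 ± 1123 (SD, n = 3 each). Calls in the authors' deposited table number 1051 of 6871 genes, 590 higher and 461 lower, with 195 and 419 protein-coding and 321 and 42 non-coding RNA genes among them.

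The libraries that stand apart were read separately. Summed over tRNA genes, that library held normalised counts of 231 in wild type, 307 in rrp6Δ, 343 in med20Δ and 2610 in the double mutant, and the other 2 libraries averaged 343, 374, 731 and 7655. The order of the strains was the same in both sets of libraries, with the double mutant highest. Limma covers the 31 tRNA genes with a mean of at least 10 over the 12 libraries, of which 6 reach that mean without the double mutant, so the filter favours genes high in it. By limma 30 of these 31 rose with all libraries, 106 of 164 rose with no filter on low counts, and 25 to 33 genes rose when any 1 library was left out. The 5.8S rRNA total also differs between these libraries, at 615 against 8250 in wild type and 4057 against 8846 in the double mutant.

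**Figure D2:**
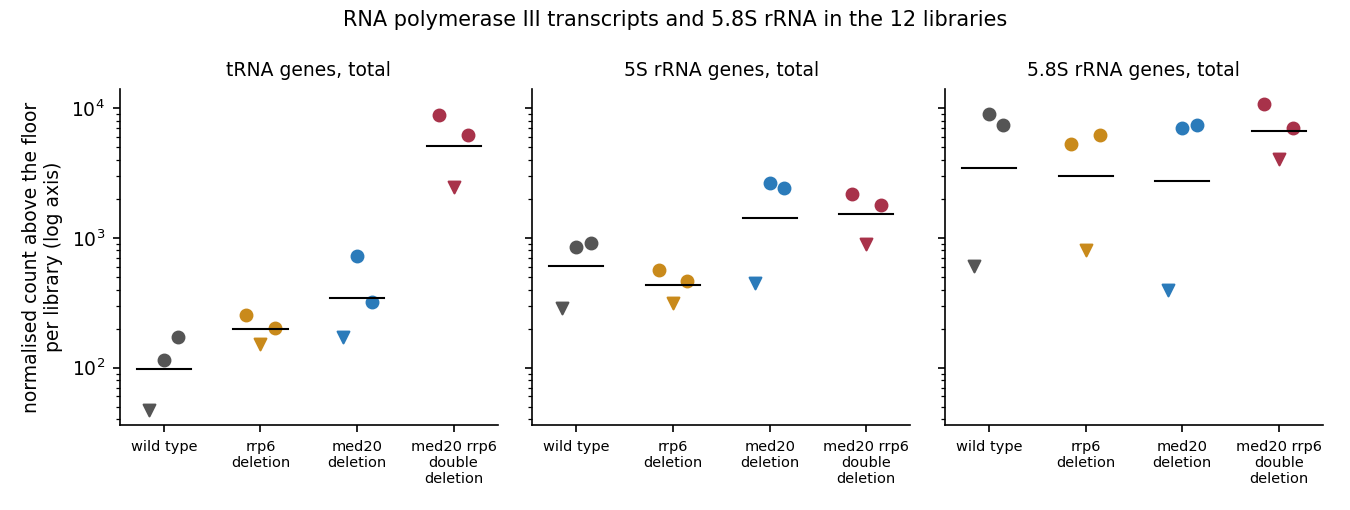
Normalised counts above the floor summed over tRNA, 5S rRNA and 5.8S rRNA genes in each of the 12 libraries, on a log axis, with a bar at the geometric mean of each strain and a triangle for the library with the lowest 5.8S rRNA in its strain. The lowest tRNA total of the double mutant, 2467, lies above the highest of the other 9 libraries, 722.

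Some genes of other small RNA classes were also called higher. Of 53 snoRNA genes 15 rose (18 adjusted over the list alone), with snR42 at 109.7-fold, sno12 at 89.9-fold and sno20 at 66.6-fold in the authors' deposited table. By Fisher's exact test the adjusted p was 0.000201, and by camera the adjusted p = 0.252 with an estimated correlation. The snRNA genes snu2 and snu3 rose 10.3- and 48.2-fold in the authors' deposited table, 2 of 10 (5 adjusted over the list alone; Fisher's exact test, adjusted p = 0.513; camera, adjusted p = 0.421 with an estimated correlation). Limma called 7 of these 10 list members with all libraries and 2 without double mutant 1. The list includes 3 genes annotated as protein-coding. Of the 7 annotated as snRNA, limma called 6 higher. Their median log2 was 4.48 in the authors' deposited table, against 3.42 over the list. Of 46 rRNA genes 6 rose (9 adjusted over the list alone; Fisher's exact test, adjusted p = 0.585), SPRRNA.32 from 43.3 ± 8.93 to 129 ± 28.3 in recovered counts (SD, n = 3 each). Their limma count of 7 was 2 without double mutant 1, double mutant 3 or wild type 1 (camera, adjusted p = 0.542 with an estimated correlation). The snRNA totals were 219 in the library of the double mutant that stands apart and 3067 on average in its others. None of 13 Tf2 genes was called (DESeq), 13 had an unadjusted p under 0.05, 13 rose adjusted over the list alone, and limma called 13. That limma count was 0 without wild type 1 or double mutant 3, 1 without double mutant 1 and 8 without wild type 3 (camera, adjusted p = 0.437 with an estimated correlation).

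Of 1492 other non-coding RNAs, 322 rose (358 adjusted over the list alone), 21.6% against 4.98% of other genes, and 42 fell (46 adjusted over the list alone), 2.82% against 7.79%. That share had an adjusted p = 1.04e-73 and 3.44e-12 for higher and lower by Fisher's exact test, while camera gave an adjusted p = 0.0189 with an estimated correlation for higher levels. SPNCRNA.1511 rose 296-fold, and SPNCRNA.1307, SPNCRNA.1105 and SPNCRNA.1471 stood at -5.69, -4.02 and -3.51 in the authors' deposited table. Among the 11 Mmi1 targets 8 rose (10 adjusted over the list alone), mcp7 23.6-fold in the authors' deposited table. For this list Fisher's exact test gave an adjusted p = 4.06e-06 and camera an adjusted p = 0.0623 with an estimated correlation. Of the 129 genes named for meiotic expression 23 rose and 4 fell (26 and 5 adjusted over the list alone), with meu1 at 16.6-fold in the authors' deposited table. The adjusted p was 0.00433 for higher calls by Fisher's exact test, and camera gave adjusted p = 0.125 with an estimated correlation. The 4 that fell were meu34, mug110, mug166 and mcp60, the last of which encodes a mitochondrial chaperonin.

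Of 141 ribosomal protein genes in the double mutant, 38 fell and 2 rose (47 and 3 adjusted over the list alone; Fisher's exact test, lower, adjusted p = 7.71e-13), with rps1401 at -1.69, rpl802 at -1.65 and rpl1603 at -1.65 in the authors' deposited table, where rpl3002 and rpl4102 rose, at 1.35 and 1.13. Their median of -0.80 stood at percentile 7.24 of lists matched on expression (adjusted p = 0.285), and camera, over 23 of them, gave an adjusted p = 0.5 with an estimated correlation. On the component of the libraries that stand apart, 6 of 23 scored positive, with a median score of -0.48 against 0.09 for all genes scored. Of 57 ribosome biogenesis genes 8 fell (6 adjusted over the list alone; Fisher's exact test, adjusted p = 0.187), utp13 most at -1.19 in the authors' deposited table. The RNA polymerase III machinery had 1 call of 23, sfc6 of the transcription factor TFIIIC, at -1.18 in the authors' deposited table (1 adjusted over the list alone).

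The cell separation genes fell here as well, 8 of 10 (8 adjusted over the list alone), with eng1 at -4.17 and adg1 at -3.87 in the authors' deposited table. Against all other genes this had an adjusted p = 2.04e-07 (Fisher's exact test) and, in camera, an adjusted p = 0.125 with an estimated correlation. Flocculation genes fell in 5 of 17 cases, pfl7, pfl3, lkh1, pfl2 and cbf12 (5 adjusted over the list alone). Fisher's exact test gave them an adjusted p = 0.0213, and camera an adjusted p = 0.3 with an estimated correlation. Core stress genes rose in 8 of 25 cases (8 adjusted over the list alone; adjusted p = 0.0049, Fisher's exact test; camera, adjusted p = 0.503 with an estimated correlation), zym1 24.9-fold and hsp16 6.45-fold in the authors' deposited table. In the glucose and carbon list of 26, 6 fell and 3 rose (6 and 3 adjusted over the list alone; Fisher's exact test, lower, adjusted p = 0.0302; camera, adjusted p = 0.893 with an estimated correlation). The glycolytic aldolase fba1 was at -1.81, while fbp1, the enzyme of gluconeogenesis, rose 8.55-fold and gal10 and gal7 5.40- and 2.29-fold in the authors' deposited table. Of 8 phosphate genes pho84, gde1, pho4 and vtc4 fell and tgp1 rose (4 and 1 adjusted over the list alone; Fisher's exact test, lower, adjusted p = 0.0062; camera, adjusted p = 0.437 with an estimated correlation), with pho84 at -1.84 and tgp1 5.88-fold higher in the authors' deposited table.

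The other lists are given as calls in the authors' deposited table, with counts adjusted over the list alone in parentheses and no adjusted Fisher p under 0.05. Of 17 S-phase genes cdc22, cdt2 and mik1 fell (3), of 19 mitosis genes slp1, chs2 and klp5 fell (3), and of 10 housekeeping controls fba1, adh1 and nda2 fell (4). Of 18 exosome genes mtr4, dis3 and rrp6 fell (3), of 22 Mediator subunits med18 and med20 fell (2), and of 21 heterochromatin and RNAi factors clr2 fell (0). The chaperone list of 18 had hsp16 higher and ssa2, hsp90 and mcp60 lower (3 and 4), the histone list of 11 hht2 higher and hht1 lower (1 and 2), and the iron list of 16 shu1 higher and ctr4 lower (1 and 1). Nitrogen starvation genes numbered 19, with amt3 and isp6 higher and put4 and aat1 lower (2 and 2). Among 48 subtelomeric genes nrg1, tht2, SPAC186.04c and SPBC1348.07 rose and mfs1, mfs2 and SPBC1348.10c fell (4 and 3). Of 3 auxotrophy markers ura4 and his2 fell (3), and of 7 pyrimidine and leucine genes ura1 and ura3 fell (3). Medians that passed the percentile test in the authors' deposited table were those for S phase (-0.69, adjusted p = 0.00412), ribosome biogenesis (-0.55, adjusted p = 0.0246), snoRNA (1.14, adjusted p = 0.00283), snRNA (3.42, adjusted p = 0.0011), rRNA (1.16, adjusted p = 0.0246), Tf2 (1.48, adjusted p = 0.0011), cell separation (-2.32, adjusted p = 0.0011), flocculation (-0.57, adjusted p = 0.0346), core stress (0.31, adjusted p = 0.0011), Mmi1 targets (2.58, adjusted p = 0.0044), tRNA (2.72, adjusted p = 0.0011) and other non-coding RNA (0.81, adjusted p = 0.0011). Camera with an estimated correlation passed the last. The lists for Tf2 elements, M cells, P cells, mating pheromone and centromere with kinetochore held 60 members and 0 calls (DESeq), with 18 at an unadjusted p under 0.05 and 20 of 57 called by limma.

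Protein-coding genes with the largest increases in the double mutant were fub2, eno102, zym1, mcp7, pdc201 and meu1, from 79.2-fold (adjusted p = 0.0162) to 16.6-fold (adjusted p = 3.03e-17), in the authors' deposited table. Besides the deleted genes and ura4, SPBPB10D8.02c, SPBPB7E8.01 and eng1 fell most, at -5.06, -4.54 and -4.17 in the authors' deposited table. As a share of all normalised counts, tRNA genes took 0.0012% in wild type and 0.0356% in the double mutant, snoRNA genes 0.0101% and 0.281%, and other non-coding RNAs 0.798% and 2.31%, as summed from the authors' deposited table. The rRNA genes took 2.60% in wild type and 6.40% in the double mutant, with 3.14% in rrp6Δ and 3.70% in med20Δ.

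**Figure D3:**
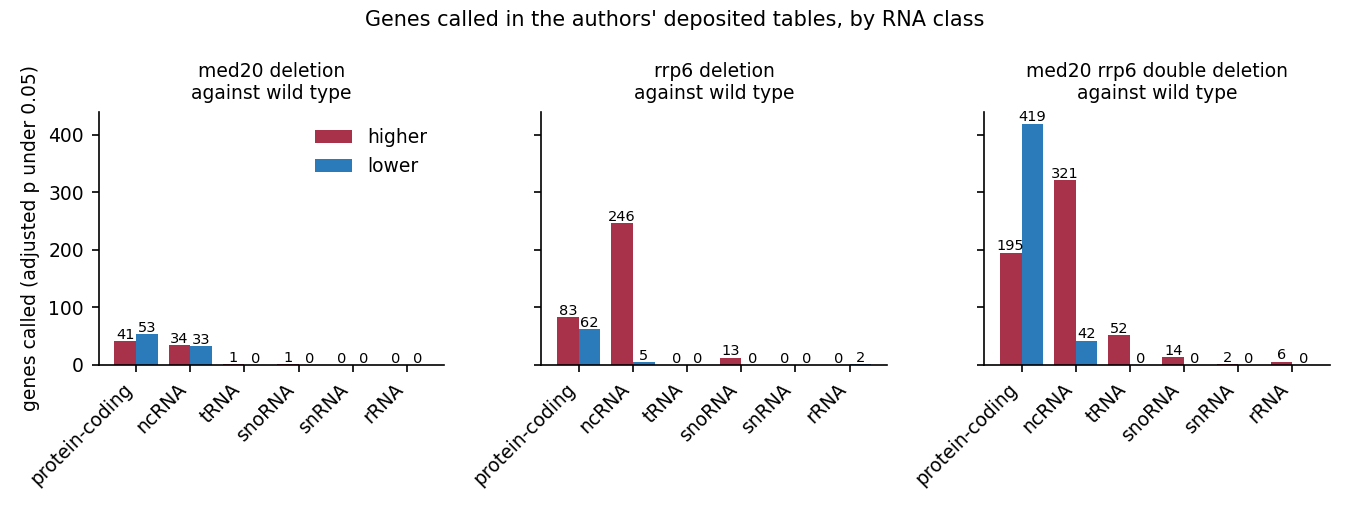
Number of genes called higher and lower at a deposited adjusted p under 0.05 in each RNA class, for each mutant against wild type. Bars for higher and lower stand side by side in different colours, both rising from 0. In rrp6Δ the 246 higher non-coding RNAs outnumber the 83 higher protein-coding genes, and in the double mutant 52 tRNA genes are higher and none is lower.

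The single mutants' calls recurred in the double mutant. Of the 77 genes higher in med20Δ, 59 were also higher in the double mutant, and of the 86 lower ones 61 were lower there, against 6.61 and 5.77 for independent lists, in the authors' deposited tables. Of the 342 higher and 69 lower in rrp6Δ, 233 and 39 recurred in the double mutant, against 29.4 and 4.63. The single mutants shared 21 higher and 12 lower genes, against 3.83 and 0.864. Across the 3 tables, 31 genes were called in all, among them eng1 and SPBPB7E8.01, and 689 were called in the double mutant alone, a count that tests no difference between strains. All 3 comparisons use the same wild-type libraries, which with no effect at all gave a simulated covariance of 0.0591 between fold changes (correlation 0.499) and 0 shared calls over 100 simulations. By limma the covariance was 0.434 between med20Δ and the double mutant (correlation 0.624), 0.622 between rrp6Δ and the double mutant (correlation 0.724) and 0.154 between the single mutants (correlation 0.333), across 5990 genes that are not independent. Part of the excess may come from the shared controls, as 3 wild-type libraries cannot be split.

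Beside med20Δ, the double mutant lacks Rrp6 as well, but it also lacks ura4, which the other 3 strains express, so differences particular to the double mutant, interactions among them, are confounded with that locus. Mating type and auxotrophic alleles differ with the deletions too, per the labels, so any comparison of strains may be confounded with them. Non-coding RNAs and Mmi1 targets were again higher. Recovered counts of SPNCRNA.942 were 51.7 ± 21.7 in med20Δ and 3358 ± 655 in the double mutant (SD, n = 3). Those of rec25, a meiotic recombination gene outside the lists, were 32.4 ± 11.5 and 271 ± 68.6. By limma, the test added after seeing the data, SPNCRNA.942 rose by 6.06 ± 0.37 (log2, SE, adjusted p = 3.35e-07), rec25 by 3.06 ± 0.31 (adjusted p = 2.94e-05) and meu10, of spore wall assembly, by 3.57 ± 0.29 (adjusted p = 3.96e-06). Of 11 Mmi1 targets 10 rose (11 adjusted over the list alone; camera, adjusted p = 0.0481 with an estimated correlation). Of 1170 non-coding RNAs 322 rose and 12 fell (391 and 16 adjusted over the list alone; camera, adjusted p = 0.00305 with an estimated correlation). Among the 31 tRNA genes passing the filter 24 rose (83 of 164 with no filter; 30 of 31 adjusted over the list alone; camera, adjusted p = 0.0892 with an estimated correlation). Of 35 snoRNA genes 15 rose and 1 fell (15 and 1 adjusted over the list alone; camera, adjusted p = 0.281 with an estimated correlation), of 10 members of the snRNA list 5 rose (7; 0.388) and of 45 subtelomeric genes 17 rose (20; 0.0892). Of the 7 genes annotated as snRNA, 5 rose. The iron genes frp1, a ferric reductase, and str1, a siderophore transporter, fell by 3.31 and 2.78 (limma, adjusted p = 0.000433 and 0.0238). Of 16 iron genes these 2, fip1, fio1 and str2 fell (5 adjusted over the list alone; camera, adjusted p = 0.545 with an estimated correlation), in a list that moves with the libraries that stand apart, 13 of 15 members scoring positive on that component. In all, limma called 541 genes higher and 327 lower of 5990. The deposited log2 fold changes of the authors' deposited tables differed by at least 1 for 673 genes, 471 up and 202 down (547 and 117 after re-centring on the median protein-coding gene).

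Beside rrp6Δ, the double mutant lacks Med20 as well, with the same difference at ura4. Recovered counts of SPCTRNATHR.10 were 8.19 ± 6.41 in rrp6Δ and 1110.5 ± 1064 in the double mutant, and those of SPBTRNAARG.05 1.73 ± 1.35 and 206 ± 174 (SD, n = 3). By limma 29 of the 31 tRNA genes passing the filter rose (96 of 164 with no filter; 30 of 31 adjusted over the list alone; camera, adjusted p = 0.143 with an estimated correlation), SPCTRNATHR.10 by 6.04 ± 1.47 (log2, SE, adjusted p = 0.0214). Other RNAs without poly(A) tails moved with them, which leaves carry-over open. Higher were 8 of 38 rRNA genes (26 adjusted over the list alone, median 1.88; camera, adjusted p = 0.515 with an estimated correlation), 7 of 35 snoRNA genes (8 and 1 lower; 0.582) and 3 of 10 members of the snRNA list (7, median 2.32; 0.524). Of the 7 genes annotated as snRNA, 3 were higher, with a median of 3.52. The metallothionein gene zym1 rose by 4.25 ± 0.38 and hsp16 by 3.49 ± 0.52 (limma, adjusted p = 3.06e-05 and 0.00113). Of 24 core stress genes 6 rose (7 adjusted over the list alone; camera, adjusted p = 0.582 with an estimated correlation). The cell separation genes fell in 8 of 10 cases (8 adjusted over the list alone; camera, adjusted p = 0.165 with an estimated correlation). Among single genes adg1 fell by 3.21 (limma, adjusted p = 4.92e-05) and SPBPB10D8.02c fell by 3.56 (adjusted p = 0.0001). Limma called 272 genes higher and 236 lower of 5990. The authors' deposited tables differed by at least 1 on the log2 scale for 504 genes, 291 up and 213 down.

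The interaction asks whether the double mutant departs from the product of the single effects. SPNCRNA.863, an intergenic RNA, had recovered counts of 497 ± 214 in wild type, 749 ± 179 in med20Δ, 97.8 ± 5.11 in rrp6Δ and 5941 ± 1451 in the double mutant (SD, n = 3), an interaction of 5.24 ± 0.41 (limma, log2, SE, adjusted p = 9.61e-06). The meiotic gene meu10 was at 59.1, 54.9, 144 and 639 in the same order (limma, 2.25 ± 0.41, adjusted p = 0.0358). The levels of rec11 were 13.3, 48.5, 279 and 206 (limma, -2.27 ± 0.41, adjusted p = 0.0358). Of 31 tRNA genes SPBTRNAGLY.03, SPBTRNAGLY.06, SPBTRNAGLY.07 and SPBTRNAGLY.08, named after their values were seen, had a positive interaction (20 of 31 adjusted over the list alone, 20 of 164 over all genes with no filter), the median of all 31 was 3.03, and camera gave an adjusted p = 0.061 with an estimated correlation. Most of the 31 lie near the floor in the other strains, where a positive value can arise without a joint effect. The number of called tRNA genes was 0 without double mutant 1 and 8 without double mutant 2. Of 45 subtelomeric genes 0 were called by limma over all genes, 14 were positive adjusted over the list alone, and the median was 1.13 (camera, adjusted p = 0.0299 with an estimated correlation). Limma called 14 genes of 5990, 9 positive and 5 negative, the latter being ura4, new25, rec11, SPNCRNA.1298 and SPNCRNA.1078. Leaving out any 1 library gave 4 to 24 genes. The fold changes of the authors' deposited tables departed by at least 1 for 328 genes, 210 up and 118 down.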

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

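The limma and camera tests and the test of each explanation below were chosen after the results they bear on had been seen. The limma interaction of the deletions differed from 0 for 14 genes, and that difference between the effect of a deletion with and without the other is what brought them here. Among them are 4 tRNA genes, med20 itself (2.43 ± 0.42, log2, SE), whose level was 24.8 in the double mutant and 5.06 in med20Δ, and ura4 (-8.45 ± 0.37). Camera gave an interaction for 7 gene lists with a preset correlation and for 2 with an estimated one, the subtelomeric genes and the auxotrophy markers, of which ura4 and his2 were tested. Of 100 splits of the 12 libraries into groups of 3, drawn at random with the real one included, 7 gave as many interaction genes as the real groups (14) and the highest other gave 1021. Such splits place the strains' own differences in the contrast, a structure of the samples to which the 1021 genes point, so they do not measure chance for the interaction. For the 5 comparisons of 2 strains, 10 splits are too few for a share under 0.05, and in each of them only 1 split, the real one, reached the real count of 156, 428, 1381, 604 or 446 genes, the highest other being 0.

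The first pattern is the higher level of tRNA in the double mutant. Reads shared between copies of 1 kind of tRNA as the whole cause are argued against by called genes of 17 kinds among 21 measured. Reads shared within each kind stay possible, so the called genes may not be separate signals. Against a single library as the whole cause stands the lowest total above the floor in the double mutant, 2466.9. The highest elsewhere was 721.604. Carry-over of RNA without poly(A) tails stays open: the lowest ratio of tRNA to 5.8S rRNA in a double mutant library was 0.6435 and the highest of the 9 others 0.8560 in counts as recovered, 0.6085 and 0.4301 with 1 count taken off each gene, a treatment taken up after the overlap was seen, and 0.6348 and 0.5785 with genes at the floor set to 0, while ratios to 5S rRNA were separated in all 3 (2.7897 and 0.8750 as recovered). A hypothesis is that loss of Med20 may raise tRNA transcripts that Rrp6 otherwise removes: the log2 tRNA total had a positive interaction of 2.8908 ± 1.0084 (SE, permutation test of residuals, two-sided, p = 0.0242) with 1 count taken off each gene and of 2.8470 ± 0.9061 (permutation test of residuals, p = 0.0186) with genes at the floor set to 0. Carry-over, the ura4 difference of the double mutant, and the share of a tRNA that carries a tail, which poly(A)-selected libraries cannot separate from its amount, would each have to be ruled out first. All rRNA genes together also took their largest share of counts in the double mutant (6.40%, against 2.60% in wild type), the direction that carry-over would give.

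The second pattern is the library of each strain that stands apart from its other 2. In 4 of 4 strains this library is also the one with the lowest 5.8S rRNA count, which is consistent with a preparation batch shared across strains. Library depth stays open, since by counts the library set apart was the deepest of its strain in 2 strains, the shallowest in 0 and in between in 2. Growth state cannot be told apart from such a batch: 21 of 22 core stress genes scored positive on the component, and a batch grown and prepared together would show both.

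The third pattern is ura4, read at the wild-type level in the libraries labelled med20Δ although their label names ura4-D18. A copy of ura4 alone outside a deleted locus is argued against by the neighbours tam14 and new25. Their lower level was 88.3% of wild type in these libraries, while the higher was 11.7% in the double mutant. A copy that carried these neighbours as well would give the same levels and stays open. An exchange with the double mutant is argued against by rrp6, at least 933 counts in each of these libraries and at most 3 in a double mutant library, and mixed-in RNA of another strain by med20, at 0.707% of wild type beside ura4 at 107%. Also open is that the genotype in the label differs from that of the strain used. The design names no biological explanation, and none was tested.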

How the results depend on the processing

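The limma test on recovered counts, voom weights, the fit to 8 libraries and the term for the library that stands apart were chosen after seeing the data. Of 201 alternatives for the main counts and values, 137 left them within 1.5 times or on the same side of the test, 62 moved a count further, 1 strengthened and 1 weakened a result, and none reversed a direction. For single lists, 47 of 51 alternatives gave the same result, 3 a weaker and 1 a stronger one. Among these, re-centring on the median protein-coding gene is no test. It keeps the deposited p-values, turned no call, and shifts a list and its random lists alike, so its list results stayed the same by construction. The same holds for the list results with re-centring among the 201. Only the alternatives over members with a mean of at least 10 could move a single list. Under limma 100 of 102 named genes had the same result and 2, amt3 and mfm2 in rrp6Δ, a weaker one. Leaving out 1 library lost up to 9 of 30 limma calls of named genes in med20Δ (wild type 2), 10 of 38 in rrp6Δ (rrp6Δ 1), 4 of 71 in the double mutant, 9 of 48 beside med20Δ (both double mutant 1), 9 of 37 beside rrp6Δ (rrp6Δ 3) and 2 of 4 for the interaction (6 of the 12 libraries), with none reversed. No paired analysis was possible because the deposited columns are group means, and the recovered libraries carry no replicate letter. The edgeR test with TMM scaling, DESeq2 and a term for the replicate were not run, because no deposited column holds counts or a replicate; the first 2 were left out for recovered counts too, where they were possible.

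At a deposited adjusted p under 0.01, med20Δ, rrp6Δ and the double mutant had 85, 265 and 601 calls, and adjusting over protein-coding genes alone left 86, 99 and 550, where 94, 145 and 614 protein-coding genes were called over all genes. Limma called 258 genes in med20Δ and 1845 in the double mutant, where the deposited adjusted p called 163 and 1051, and 14 for the interaction, where 328 deposited fold changes departed by at least 1 on the log2 scale without a test; the cause was not tested. Shared calls at 0.01 were 8 higher and 6 lower between the single mutants, 26 and 35 between med20Δ and the double mutant, and 148 and 15 between rrp6Δ and the double mutant, since fewer genes pass. By limma they moved to 50 higher between the single mutants, 111 higher between med20Δ and the double mutant and 68 lower between rrp6Δ and the double mutant. Lists whose median passed the percentile test in rrp6Δ went from 14 to 9 over members with a mean of at least 10. With a minimum log2 change of 1, the Fisher test of rRNA genes, higher against lower, went from an adjusted p = 0.0556 to 0.0394 in rrp6Δ (0 higher) and from 0.0455 to 0.0512 in the double mutant (6 higher).

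Within limma, the counts for med20Δ, rrp6Δ, the double mutant, the double mutant beside med20Δ, beside rrp6Δ, and the interaction were 258, 482, 1845, 868, 508 and 14. At an adjusted p under 0.01 they were 88, 232, 990, 329, 191 and 5. At 0.10 they reached 428 for med20Δ, 1341 beside med20Δ and 924 beside rrp6Δ. A term for the library that stands apart raised them to 653, 946, 2785, 1841, 1424 and 69. Leaving those 4 libraries out gave 1518 beside med20Δ and 1070 beside rrp6Δ. A minimum log2 change of 1 left 1220 in the double mutant, fitting only the strains compared left 156 in med20Δ, a mean of at least 50 left 315 in rrp6Δ and 3 for the interaction, and no filter on low counts gave 35 for the interaction. Leaving out 1 library at a time gave 105 to 226 genes in med20Δ, 244 to 411 in rrp6Δ, 1136 to 1915 in the double mutant, 392 to 1032 beside med20Δ, 204 to 618 beside rrp6Δ and 4 to 24 for the interaction. Each such fit leaves 2 libraries in 1 strain. The lowest counts came without med20Δ 2, rrp6Δ 1, double mutant 1, double mutant 1, rrp6Δ 3 and double mutant 1. Others under the main count by more than 1.5 times were 121 and 148 in med20Δ (without wild type 2 or med20Δ 1), 315 and 308 in rrp6Δ (wild type 3, rrp6Δ 3), 407 beside med20Δ (med20Δ 3), and 305 and 219 beside rrp6Δ (rrp6Δ 1, double mutant 1). For the interaction they were 5 to 9 without wild type 2 or 3, rrp6Δ 1 or 3, med20Δ 1 or 3, or double mutant 3, and the highest count, 24, came without double mutant 2.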

Other observations

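The test of 5S rRNA in this part was chosen after its result had been seen. The genes named in this part were also chosen after their values were seen. The median of the subtelomeric list was -0.62 in med20Δ and -0.38 in rrp6Δ, below matched random lists, and 0.57 in the double mutant, not set apart from them, in the authors' deposited tables (percentile test, adjusted p = 0.000943, 0.000943 and 0.285; camera, adjusted p = 0.556, 0.663 and 0.437 with an estimated correlation). The predicted membrane transporter gene SPBC1348.05 had recovered counts of 38.26 ± 7.20 in wild type, 12.05 ± 2.96 in med20Δ, 15.92 ± 2.27 in rrp6Δ and 44.99 ± 13.97 in the double mutant (SD, n = 3; limma interaction 2.9997 ± 0.50, log2, SE, adjusted p = 0.0261). The transcription factor gene grt1 was at 95.1 ± 44.0, 3.24 ± 1.61, 5.14 ± 2.40 and 8.96 ± 0.990 in that order, low in all 3 mutants, with a limma interaction of 5.20 ± 0.71 (adjusted p = 0.00592); levels this near the floor can give a positive value without a joint effect of the deletions.

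RNA polymerase III also makes 5S rRNA, while 5.8S rRNA is a product of RNA polymerase I. A hypothesis is that loss of Med20 may raise 5S rRNA as well as tRNA in these libraries. The totals compared here had 1 count taken off each gene, which enlarges differences between low totals. Before that step, tRNA totals in the libraries that stand apart were 231 in wild type, 343 in med20Δ, 307 in rrp6Δ and 2610 in the double mutant. In the other libraries they averaged 343, 731, 374 and 7655 in that order. The 6 libraries without Med20 exceeded the 6 with it by 1.52 on the log2 scale for 5S rRNA (exact permutation test, two-sided, p = 0.0216, adjusted over 3 RNAs p = 0.0324), by 3.25 for tRNA (p = 0.00866, adjusted p = 0.026, exact permutation test) and by 0.42 for 5.8S rRNA (p = 0.788, exact permutation test). This test treats the 12 libraries as exchangeable, although they are 4 strains of 3. Its p-values therefore ignore the strains and the libraries that stand apart. Comparing each strain without Med20 with its partner with it, within the libraries that stand apart and within the others, the 5S difference was positive in 4 of 4 pairs (0.65 to 1.95), that of tRNA in 4 of 4 (1.86 and 1.78 in med20Δ minus wild type, 4.03 and 5.03 in double mutant minus rrp6Δ, so the pooled 3.25 joins unlike differences) and that of 5.8S rRNA in 2 of 4. In double mutant minus rrp6Δ 5.8S rRNA also rose, by 2.34 in the libraries that stand apart, more than 5S rRNA there (1.51), and by 0.59 in the others, against -0.62 and -0.18 in med20Δ minus wild type. Carry-over of RNA without poly(A) tails that differs by RNA size, and a change in tailing, stay open here too.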
